A study of Mus musculus with 24 samples.

How the data were processed

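RNA from heart ventricle of FVB mice, an inbred strain, was measured on 24 single-channel Affymetrix mouse arrays, per the labels as total RNA. The labels give 8 groups of 3 arrays each: embryonic day 12.5 (E12.5), neonates, 1 week, 4 weeks, 3-month females, 5-month males, 1-year females and a further 1-year group whose titles carry the suffix m. That suffix also marks the 5-month males, but the descriptions of the 1-year m group give no sex, so it is called the 1-year m group throughout. Sex is not given for the groups up to 4 weeks, nor is the age of the neonates in days. Titles of E12.5 samples carry 3 numbers and those of neonates 2, and the labels do not say whether arrays stand for separate animals or for pools, so the p-values measure the spread between these samples. No paired analysis was possible because the numbers in the titles do not link samples of different groups.

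The deposited values are linear probe-set signals (intensity) that the authors had already scaled: the 2%-trimmed mean over probe sets not at 0 was between 500.44 and 500.6 on all 24 arrays. The software and the settings behind these signals are not given in the sources used here, and neither are detection calls. Of 12654 probe sets, 66 are controls and 2611 hold 0 on all arrays, while none holds 0 on only some arrays. Of the remaining 9977 probe sets, 8724 carry exactly 1 gene symbol in the platform annotation, 346 carry several and 907 carry none, which gave 7417 measured genes. Symbols were checked by Entrez ID against the mouse RefSeq annotation of GRCm38.p6, where 10279 of 10298 probe sets with 1 gene matched. Chromosomes are taken from that annotation through the Entrez ID, and no probe position was computed.

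Values below the 25th percentile of the table (a signal of 14.2) were set to it and log2 was taken, without further normalization between arrays. Probe sets at 0 on all arrays counted in this percentile, so far fewer of the measured values lay below it. Probe sets above this floor on at least 3 of the 24 arrays were tested, which kept 9952 probe sets and 7406 genes. limma 3.58.1 in R 4.3.3 was fitted with 1 mean per group (lmFit, eBayes with an intensity trend, 16 residual degrees of freedom, median prior degrees of freedom 7.58), so every comparison shares its estimate of the spread with all 24 arrays. The 9 comparisons were neonate against E12.5, 1 week against neonate, 4 weeks against 1 week, young adults (the mean of 3-month females and 5-month males) against 4 weeks, both 1-year groups against young adults, 1-year females against 3-month females, the 1-year m group against 5-month males, the difference between the latter comparisons (ageing by sex), and 1-year females against the 1-year m group. A moderated F test covered any difference among the 8 groups. P-values were adjusted by Benjamini-Hochberg within a comparison, two-sided, at a threshold of 0.05. Folds are on the log2 scale with the standard error (SE) of the limma fit, and signals are means with the standard deviation (SD) over 3 arrays. The number of arrays limits the precision.

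Before the data were examined, 30 gene lists were fixed, covering cardiac, metabolic, proliferation, matrix, immune and stress genes and markers of 12 other cell types or tissues. Each gene was represented by its probe set with the highest mean signal. For 29 of these lists camera (limma) compared the members with all other genes, with a preset correlation of 0.01 between genes and, as an alternative, with the correlation estimated from the data. This made 261 tests over the 9 comparisons, adjusted over the lists within a comparison. The list of sex-linked genes served only to check the labels. Members are also counted with p adjusted over the list alone. Across the 74 called tests, the median, the mean and the camera direction of a list had the same sign. Among the 187 tests not called these differed in sign in 37.

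Genes are named by a rule fixed in advance. In each comparison these were the 8 largest rises and 8 largest falls among genes past the threshold whose arrays of 1 side all lay above all arrays of the other side, skipping clone names. To these were added the 3 members of each called list with the largest change past the threshold in the direction of the list, and the 3 members of highest signal in each called list of a cell type. For the ageing by sex comparison the 5 largest were taken. Genes outside this rule are marked as chosen after their values were seen.

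The fit and the list test were tried on simulated log2 values with independent normal noise for each probe set, which did not pass through the floor. In the comparison of neonate with E12.5, 100 probe sets per size were given a known change among 9952. They were drawn only from probe sets with a mean signal above the median, so the recovery does not cover dimmer ones. The fit recovered 60 at 2-fold and 92 at 4-fold, 0 with the wrong sign, with 12 false calls, and made 0 calls in a comparison without a change. Among 58 list tests, the list with a simulated shift was called in the comparison that held it, and 0 other calls were made. Because the simulated genes did not move together, this does not show how many lists would be called wrongly in the real data.

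The alternatives tried were quantile normalization, floors at the 5th and 40th percentiles, a pseudocount in place of the floor, no filter, a stricter filter (above the median on at least 6 arrays), no intensity trend, array weights, only the groups compared in the fit, a minimum of 2-fold, the mean over all probe sets of a gene, and leaving out each array in turn. The 5th percentile was a signal of 0, so that alternative set no floor, and the 40th was 60.8. After the data had been seen, 3 further alternatives were added: a batch term from hybridization controls, leaving out 2 arrays together, and each group of young adults alone against 4 weeks. The batch term split the arrays by the log2 ratio of the control transcripts BioB and BioC, which are added to the hybridization mix. Only the 1-year m group held arrays on both sides of this split. The term was therefore estimated from its 1st array against its 2nd and 3rd alone. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for annotation and figures. Probe sets with several or no gene symbols were tested but are not named. Raw scanner files were not analysed here.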

Results

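Gene expression was measured in the heart ventricle of FVB mice from embryonic day 12.5 (E12.5) to 1 year of age, on 24 arrays in 8 groups of 3. The title of the series names cardiac development, maturation and ageing as its subject. Each comparison sets neighbouring ages, or the sexes, against each other. The median signal of the arrays lay between 195.5 and 225.2, and log2 signals of arrays of the same group correlated with Pearson r from 0.907 to 0.939. These are correlations across probe sets, which are not independent replicates. The control probe set for 18S ribosomal RNA had group means of 5844 ± 2540 (SD) at E12.5, 894.7 ± 325 in neonates, 1581 ± 1240 at 1 week (1 array at 3018) and 307.1 ± 53.9 at 4 weeks. In 3-month females, 5-month males, 1-year females and the 1-year m group it had 362.8 ± 96.6, 916.8 ± 656, 675.4 ± 112 and 448.3 ± 254. The ratio of 3' to 5' signal of actin, a measure of RNA integrity, had group means of 0.9995, 1.189, 1.032, 1.205, 1.127, 1.401, 1.383 and 1.511 in the same order. Control probe sets for bacterial and other non-mouse transcripts gave a background: the 95th percentile of their signals was 125, and 37.9% of the tested values lay below it. A fold against a group mean under 125 therefore depends on that background. Of 9952 probe sets, 3883 (39.02%) differed among the 8 groups by limma.

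**Figure D1:**
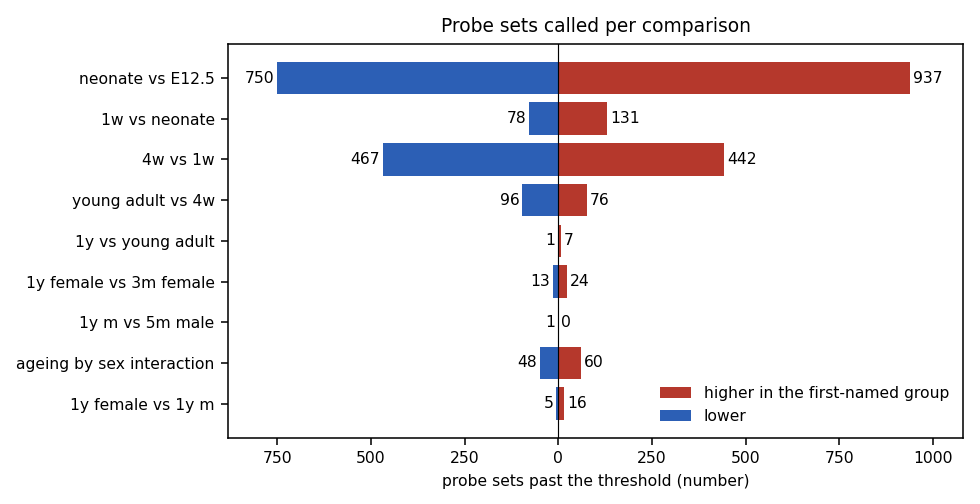
Probe sets past the threshold in each of the 9 comparisons (limma, adjusted p under 0.05), on the horizontal axis as a number, with those higher in the first-named group to the right and those lower to the left. Neonate against E12.5 gave the longest bars, 937 higher and 750 lower, and the 1-year m group against 5-month males the shortest, 0 and 1.

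The sex-linked transcripts were read as a check of the labels. Xist, the X-linked RNA of the inactive X chromosome, gave 580.3 to 1163.7 on the arrays of 3-month females and 892.2 to 1329.5 on those of 1-year females, against 6.7 to 47.2 in 5-month males and 13.1 to 88.6 in the 1-year m group. The Y-linked Eif2s3y gave 270.5 to 448.3 in 5-month males and 345.9 to 428.9 in the 1-year m group, against at most 87.2 in 3-month females and 103 in 1-year females. The Y-linked Uty had means of 186 ± 35.1 (SD) and 176 ± 35.9 in these groups, against 52.2 ± 31.2 and 54.1 ± 64.1 in the females. Kdm5d stayed below the background level in all 4 adult groups, with means from 25.6 to 67.8. In the groups with no sex given, Xist had means of 1290 ± 423 at E12.5, 880 ± 1400 in neonates, 464 ± 676 at 1 week and 18 ± 6 at 4 weeks. Eif2s3y had means of 234 ± 116, 348 ± 292, 190 ± 168 and 312 ± 67.9 in the same order, and Kdm5d of 71.5, 106, 43.8 and 45.6. Those of Uty were 97.1, 133, 75.8 and 151.

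From E12.5 to neonates, transcripts of the mature contractile machinery and of oxidative metabolism rose, and embryonic globins fell. Myom2 (Entrez gene 17930, chromosome 8 of GRCm38), which encodes a protein of the sarcomeric M-band, rose by 5.64 ± 0.28 (SE) on the log2 scale, from a mean signal of 36.7 ± 25.6 (SD, n = 3) to 1580 ± 177. Ckmt2, the mitochondrial creatine kinase of muscle, rose by 4.85 ± 0.24, and the oxygen-binding Mb (myoglobin) by 4.27 ± 0.27. The embryonic beta-like globin Hbb-y (Entrez gene 15135, chromosome 7) fell by 8.56 ± 0.80 on the log2 scale, from 18900 ± 5740 to 59.5 ± 36.3. Of 9952 probe sets, 1687 passed the threshold, 937 higher and 750 lower in neonates.

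Fatty acid oxidation rose as a list, with 27 of 30 measured members higher, 0 lower and 3 not past the test (27 adjusted over the list alone, camera adjusted p = 8.33e-25). Among them were Pdk4, which restrains glucose oxidation (log2 fold change 3.66 ± 0.43), and the fatty acid transporters Slc27a1 (3.47 ± 0.31) and Cd36 (3.18 ± 0.35). Oxidative phosphorylation rose with 37 of 58 members higher and 0 lower (40 adjusted over the list alone), among them the muscle isoforms Cox6a2 (1.73 ± 0.26) and Cox7a1 (1.64 ± 0.15) and the complex I subunit Ndufa8 (1.23 ± 0.15). The tricarboxylic acid cycle rose with 13 of 18 members (13 adjusted over the list alone), led by Idh2 (1.42 ± 0.14), Cs (1.01 ± 0.12) and Pdha1 (0.99 ± 0.16). Adult contractile and calcium-handling genes rose with 15 of 21 (15 adjusted over the list alone). Glycolysis genes did not move as a list, with 5 higher and 4 lower of 15 (camera adjusted p = 0.77). Fetal cardiac genes did not either, with 0 higher and 3 lower of 13 (camera adjusted p = 0.198).

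Extracellular matrix genes rose from E12.5 to neonates, with 23 of 39 higher and 2 lower (24 and 2 adjusted over the list alone). Col15a1, a basement membrane collagen, rose by 5.17 ± 0.33, the fibrillar collagen Col1a1 by 2.64 ± 0.15, and the proteoglycan Dcn by 2.60 ± 0.14. Outside that list, the matrix proteins Dpt (5.07 ± 0.30), Tnxb (4.36 ± 0.26) and Ccn3 (4.28 ± 0.52) and the cadherin Cdh13 (4.55 ± 0.29) were among the largest rises. Markers of other cell types moved with these genes. Endothelial markers rose with 7 of 20 higher and 2 lower (9 and 3 adjusted over the list alone). Among them were the tight junction protein Cldn5 (5.32 ± 0.35), the transcription factor Sox18 (2.27 ± 0.17), Aqp1 (1.78 ± 0.28) and the cadherin Cdh5 (1.13 ± 0.17). Eng had 0.50 ± 0.19 and did not pass. Epicardium and fibroblast markers, which share Col1a1, Dcn and other collagens with the matrix list, rose with 8 of 19 higher and 1 lower (8 and 2 adjusted over the list alone). Msln had 2.68 ± 0.52 and Col3a1 1.41 ± 0.25. Complement and acute phase genes rose with 5 of 11 (6 adjusted over the list alone), namely Cp (2.22 ± 0.38), C1qb (1.82 ± 0.23) and C1qa (1.68 ± 0.17) among others. Cp lay below the background level of 125 in both groups (23.6 to 107). Clock genes rose with 4 of 13 (5 adjusted over the list alone), with Per1 at 2.30 ± 0.38, Nr1d2 at 1.22 ± 0.26 and Bhlhe40 at 1.03 ± 0.21.

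Cell cycle genes fell from E12.5 to neonates, with 12 of 39 lower and 0 higher (19 adjusted over the list alone), among them the proliferation marker Mki67 (-2.18 ± 0.62), Ect2 (-2.26 ± 0.66) and Cks2 (-2.0 ± 0.57). DNA replication genes fell with 14 of 33 lower (16 adjusted over the list alone), among them the primase subunit Prim2 (-2.58 ± 0.43), the helicase cofactor Cdc45 (-2.53 ± 0.64) and the ribonucleotide reductase subunit Rrm1 (-1.73 ± 0.58). Erythroid markers fell with 13 of 18 lower (13 lower and 1 higher adjusted over the list alone). Besides Hbb-y, the embryonic globins Hba-x (-5.78 ± 0.37) and Hbb-bh1 (-5.54 ± 0.48), the red-cell anion exchanger Slc4a1 (-4.67 ± 0.50), Car2 (-4.63 ± 0.26), Hemgn (-4.61 ± 0.65) and the glucose transporter Slc2a1 (-4.28 ± 0.80) were among the largest falls, as was the steroid dehydrogenase Hsd3b6 (-5.01 ± 0.39). The adult globins did not pass the test, Hba-a1 with 0.14 ± 0.34 and Hbb-b2 with -0.23 ± 0.40, nor did Tfrc with -0.24 ± 0.23. Imprinted growth genes fell with 4 of 16 lower and 1 higher (4 and 1 adjusted over the list alone), among them the cell cycle inhibitor Cdkn1c (-2.66 ± 0.24), Nnat (-2.68 ± 0.86) and Ndn (-1.15 ± 0.31). Ribosomal protein genes fell with 15 of 28 lower (16 lower and 1 higher adjusted over the list alone), with Rpl13a at -2.12 ± 0.27, Rps19 at -1.73 ± 0.19 and Rpl10a at -0.92 ± 0.16. The calls of Mki67, Ect2, Cks2, Cdc45, Rrm1, Nnat and Ndn were each lost without some single array of these groups, with adjusted p up to 0.247 for Nnat.

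Of the 16 lists called for neonate against E12.5, 14 kept their call with an estimated correlation. Antigen presentation (4 of 16 higher, 4 adjusted over the list alone, with Psmb8 at 2.19 ± 0.37, H2-D1 at 1.42 ± 0.17 and H2-K1 at 1.41 ± 0.20) had adjusted p = 0.111 with an estimated correlation. Adipocyte markers (3 higher and 1 lower of 14, 4 and 1 adjusted over the list alone) had adjusted p = 0.0775 with an estimated correlation. Their members were Cidea at 3.40 ± 0.39, Lipe at 3.04 ± 0.35, Fabp4 at 1.53 ± 0.25, Scd2 at -0.59 ± 0.20 and Lep, not past the test, at 0.46 ± 0.17. No call was made for macrophages (3 higher of 17), T and B lymphocytes (0 of 15), atrial myocytes (1 higher of 11), smooth muscle (5 higher and 2 lower of 11), skeletal muscle (1 higher and 3 lower of 17), liver (1 higher and 1 lower of 17), lung epithelium (0 of 6) or neurons and Schwann cells (1 higher of 16). The same holds for interferon response (2 higher and 1 lower of 19), senescence (2 higher and 1 lower of 13) and immediate early and heat shock genes (4 higher and 3 lower of 27).

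**Figure D2:**
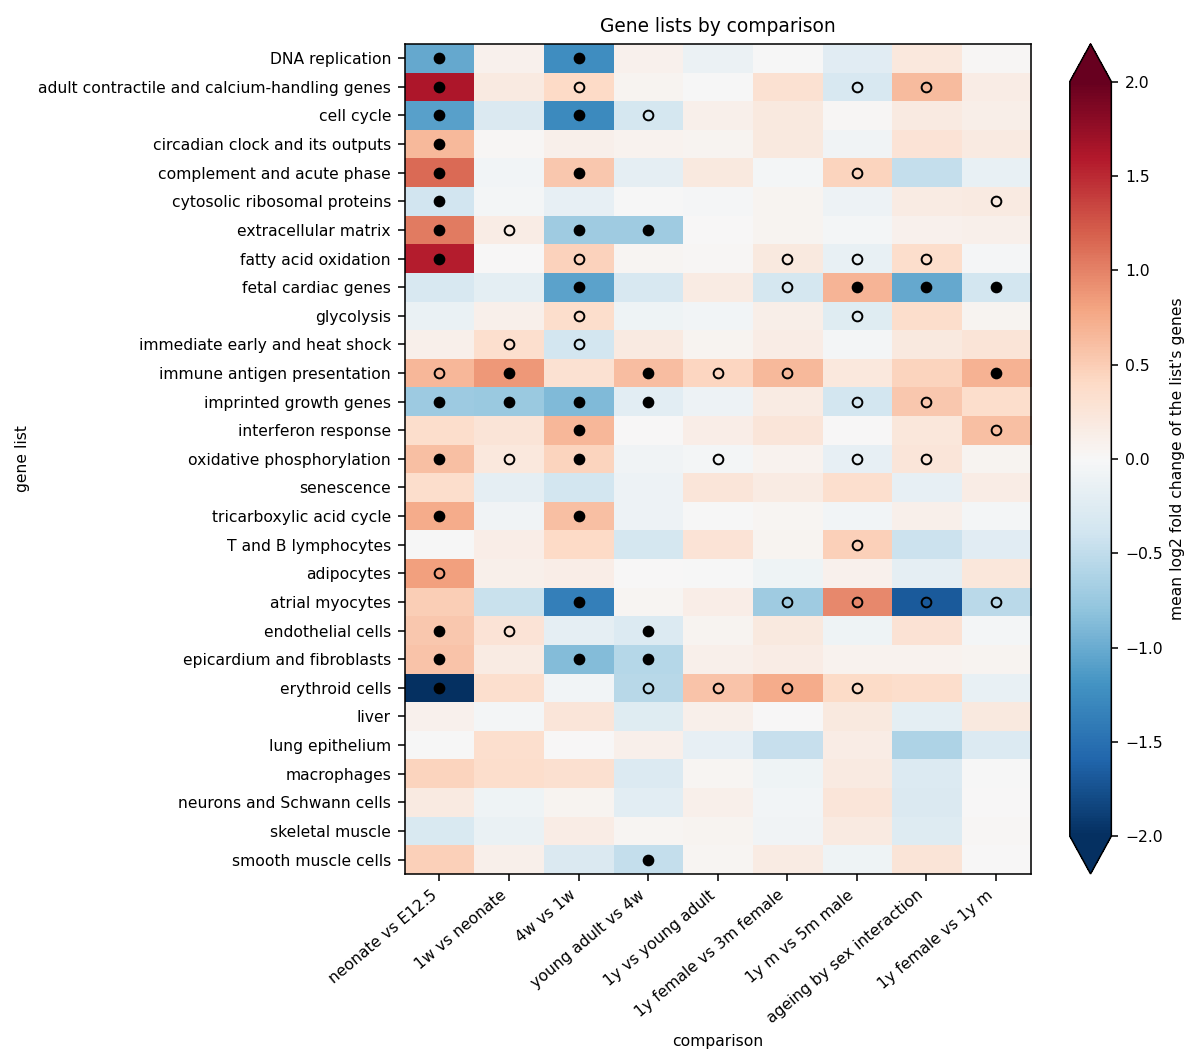
Mean log2 fold change of the genes of each of 29 lists (vertical axis) in each of the 9 comparisons (horizontal axis), as a colour scale from -2 to 2 with darker ends beyond. Filled circles mark the 37 camera calls kept with an estimated correlation and open circles the other 37. In neonate against E12.5, contractile genes and fatty acid oxidation had means of 1.62 and 1.57 and erythroid markers of -2.72.

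From neonates to 1 week of age, genes of immune antigen presentation rose and imprinted growth genes fell. Mapt (Entrez gene 17762, chromosome 11), which encodes the microtubule-associated protein tau, rose by 5.40 ± 0.30 on the log2 scale, from 26.0 ± 9.8 (SD, n = 3) to 1060 ± 242. Psmb9, a subunit of the immunoproteasome, rose by 2.75 ± 0.40. The probe sets annotated to the class I genes H2-D4 (3.30 ± 0.52), H2-K2 (2.65 ± 0.39), H2-K1 (1.78 ± 0.20) and H2-D1 (1.75 ± 0.17), whose sequences are alike enough to share signal, rose as well. Bmp7 (Entrez gene 12162, chromosome 2), a growth factor of the bone morphogenetic protein family, fell by 3.12 ± 0.44 on the log2 scale, from 536 ± 110 to 61.0 ± 4.3. In all, 209 probe sets passed, 131 higher and 78 lower at 1 week.

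Antigen presentation rose with 5 of 16 members higher and 0 lower (8 adjusted over the list alone), and camera gave adjusted p = 4.79e-09, or 0.014 with an estimated correlation. Imprinted growth genes fell with 2 of 16 lower (4 adjusted over the list alone, adjusted p = 0.00842 with an estimated correlation), namely Dlk1 (-1.92 ± 0.28) and Peg3 (-1.45 ± 0.21). For the other 4 called lists the call was lost. Oxidative phosphorylation, with 8 of 58 higher (15 adjusted over the list alone) and Ndufv3 at 1.05 ± 0.17, Cox7a1 at 0.84 ± 0.15 and Ndufa3 at 0.77 ± 0.15, had adjusted p = 0.169 with an estimated correlation. Endothelial markers (2 of 20, 4 adjusted over the list alone), extracellular matrix (2 of 39, 5 adjusted over the list alone) and immediate early genes (2 of 27, 2 adjusted over the list alone) each had adjusted p = 0.0649 with an estimated correlation. Their members past the test were Aqp1 (1.44 ± 0.28) and Sox18 (0.83 ± 0.17), Dcn (0.84 ± 0.14) and Fbln1 (0.82 ± 0.18), and Jun (1.36 ± 0.22) and Egr1 (0.98 ± 0.24), while Cdh5 (0.59 ± 0.17) and Eng (0.29 ± 0.19) did not pass.

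The other large rises at 1 week were the transporter Abcc1 (2.51 ± 0.45), Vtn (2.72 ± 0.63), Amelx (2.58 ± 0.66) and Galnt10 (2.47 ± 0.57). The other large falls were Rabgap1l (-3.02 ± 0.74), Snhg5 (-2.93 ± 0.52), the neuropeptide Vip (-2.81 ± 0.72), Spock2 (-2.62 ± 0.59), Cckar (-2.57 ± 0.67), Cyp1b1 (-2.51 ± 0.66) and Bex4 (-2.45 ± 0.33). Snhg5 (121 to 11.2) and Cckar (94 to 13.6) lay below the background level of 125 in both groups. The higher group mean of Abcc1, Vtn, Amelx, Vip and Cyp1b1 was 131 to 174, under the highest non-mouse control signal of 193.6. These folds depend on the background. With only the 6 arrays of these groups in the fit, 16 probe sets passed in place of 209, and Mapt was the only gene of those named in this comparison that kept its call besides Bmp7, Bex4 and Peg3. The calls of Vtn, Amelx, Galnt10, Egr1, Sox18, Fbln1, Cyp1b1, Cckar, Spock2, Vip and Rabgap1l were each lost without some single array, with adjusted p up to 0.403 for Cckar over all alternatives. The count fell to 114 without the 3rd array of 1 week, 118 without the 1st and 109 without the 2nd of the neonates.

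From 1 to 4 weeks the fetal troponin isoform and the proliferation programme fell, and genes of mitochondrial energy metabolism rose. Tnni1 (Entrez gene 21952, chromosome 1), the slow skeletal troponin I of the fetal heart, fell by 5.80 ± 0.24 on the log2 scale, from 25200 ± 3140 (SD, n = 3) to 484 ± 236. Kcne1, a subunit of a potassium channel, fell by 5.01 ± 0.41, and Cks2, a partner of the cyclin-dependent kinases, fell by 4.50 ± 0.57. Ces1d (Entrez gene 104158, chromosome 8), a carboxylesterase, rose by 4.75 ± 0.59, from 19.9 ± 1.3 to 537 ± 57.3. Of 909 probe sets past the threshold, 442 were higher and 467 lower at 4 weeks.

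Cell cycle genes fell with 18 of 39 lower and 1 higher (25 and 1 adjusted over the list alone), among them Prc1 (-3.41 ± 0.50) and Racgap1 (-3.27 ± 0.60), which act in cytokinesis, as does Anln (-3.21 ± 0.57) outside the list. DNA replication genes fell with 13 of 33 lower (23 adjusted over the list alone), including the helicase subunit Mcm2 (-2.48 ± 0.59) and both ribonucleotide reductase subunits Rrm2 (-2.46 ± 0.55) and Rrm1 (-2.34 ± 0.58). Imprinted growth genes fell with 7 of 16 lower (8 adjusted over the list alone), led by Mest (-3.23 ± 0.62), Plagl1 (-2.45 ± 0.67) and the growth factor Igf2 (-2.39 ± 0.15), for which another probe set had the opposite sign. Fetal cardiac genes fell with 6 of 13 lower and 1 higher (6 and 1 adjusted over the list alone). Atrial markers fell with 4 of 11 lower (5 adjusted over the list alone), among them the atrial light chain Myl7 (-4.05 ± 0.92), Dkk3 (-3.03 ± 0.42) and the natriuretic peptide Nppa (-1.53 ± 0.28). Myl4 had -0.83 ± 0.52 and did not pass. Myl7, Myl4 and Nppa stand in both of these lists. The 3 1-week arrays read 12318.2 to 16292.8 for Myl7 against 699.6 to 980.3 at 4 weeks.

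Extracellular matrix genes fell from 1 to 4 weeks, with 21 of 39 lower and 1 higher (24 and 3 adjusted over the list alone). Among them were Nid2 (-2.75 ± 0.54), the matricellular Postn (-2.38 ± 0.28) and Tnc (-2.17 ± 0.63). Epicardium and fibroblast markers, partly the same genes, fell with 7 of 19 lower (9 adjusted over the list alone), including the retinoic acid enzyme Aldh1a2 (-2.04 ± 0.60) and the collagens Col1a2 (-1.67 ± 0.15), Col1a1 (-1.65 ± 0.15) and Col3a1 (-1.29 ± 0.25). Dcn had 0.28 ± 0.14 and did not pass.

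Oxidative phosphorylation rose with 17 of 58 higher (27 adjusted over the list alone, adjusted p = 0.0353 with an estimated correlation), among them Ndufs4 (2.18 ± 0.50), Cox7a1 (1.61 ± 0.15) and Uqcrb (1.35 ± 0.19). The tricarboxylic acid cycle rose with 10 of 18 (11 adjusted over the list alone), including Sucla2 (1.34 ± 0.22), Suclg1 (1.01 ± 0.12) and Dlat (0.96 ± 0.15). Complement and acute phase genes rose with 3 of 11 (3 adjusted over the list alone), namely Cp (2.21 ± 0.38), C1qc (0.90 ± 0.22) and C1qa (0.74 ± 0.17). Interferon response genes rose with 2 of 19 (2 adjusted over the list alone, adjusted p = 0.0444 with an estimated correlation), the GTPase Iigp1 (2.95 ± 0.60) and Ifi204 (1.45 ± 0.39). For 4 further called lists the call was lost. Fatty acid oxidation, with 11 of 30 higher and 1 lower (16 and 1 adjusted over the list alone) and Lpl at 1.78 ± 0.29, Cd36 at 1.22 ± 0.35 and Ech1 at 1.21 ± 0.16, had adjusted p = 0.068 with an estimated correlation. Contractile genes, with 6 of 21 higher (9 higher and 1 lower adjusted over the list alone) and Hrc at 1.51 ± 0.15, Kcnj11 at 1.09 ± 0.28 and Myom1 at 0.93 ± 0.15, had adjusted p = 0.0628 with an estimated correlation. Glycolysis, with 6 higher and 1 lower of 15 (6 and 2 adjusted over the list alone), among them the insulin-responsive glucose transporter Slc2a4 (1.63 ± 0.25), Hk2 (1.43 ± 0.14) and Ldhb (0.96 ± 0.21), had adjusted p = 0.111 with an estimated correlation. Immediate early genes, with 6 lower and 1 higher of 27 (8 and 1 adjusted over the list alone) and Klf2 at -1.78 ± 0.56, Atf3 at -1.22 ± 0.25 and Jun at -1.20 ± 0.22, had adjusted p = 0.0819 with an estimated correlation.

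The other large rises at 4 weeks were B3galnt2 (3.05 ± 0.62), the purine receptor P2ry1 (2.83 ± 0.65), the aldehyde oxidase Aox1 (2.82 ± 0.40), the retinoid receptor Rxrg (2.70 ± 0.52), the transcription factor Zbtb16 (2.66 ± 0.48) and the class II gene H2-Aa (2.57 ± 0.45). P2ry1 (16.4 to 117) lay below the background level of 125 in both groups, and B3galnt2 (14.4 to 134) was near it at 4 weeks. With only the 6 arrays of these groups in the fit, 586 probe sets passed in place of 909, and Iigp1, Rxrg, H2-Aa, Sucla2, Cd36, Ifi204, Klf2, Rrm1 and Plagl1 no longer did. The calls of Ifi204, Cd36, Kcnj11, C1qc, Klf2, Aldh1a2, Tnc, Rrm1, Plagl1 and Mcm2 were each lost without some single array, with adjusted p up to 0.225 for Klf2.

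**Figure D3:**
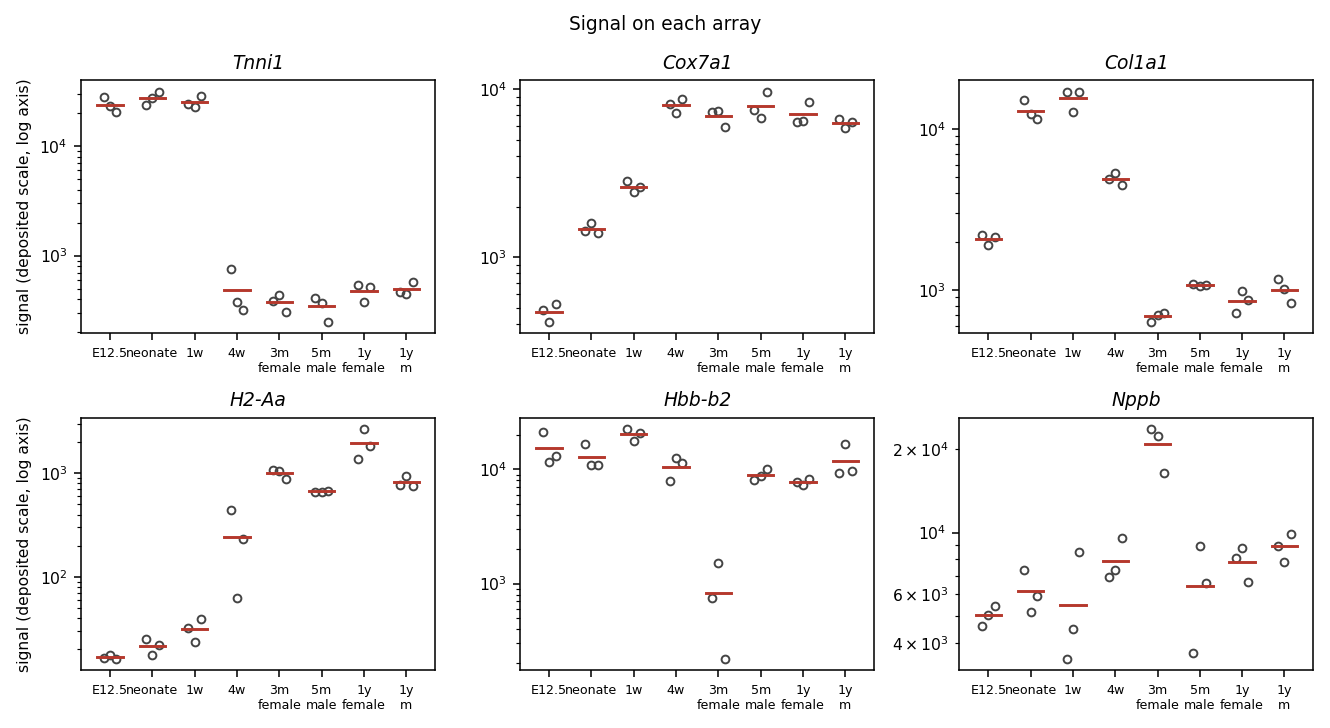
Signal of 6 genes on each array (circles, log axis, scale as deposited) in the 8 groups along the horizontal axis, with the group mean as a line. Tnni1 lay between 20598.1 and 31345.9 up to 1 week and between 249.9 and 754.5 from 4 weeks on, and Hbb-b2 was low in 3-month females, with a mean of 823.

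From 4 weeks to young adulthood (the mean of 3-month females and 5-month males) genes of the extracellular matrix fell and genes of antigen presentation rose. Eln (Entrez gene 13717, chromosome 5), which encodes elastin, fell by 2.78 ± 0.16 on the log2 scale, from 5580 ± 483 (SD, n = 3) to 839 ± 290 in 3-month females and 818 ± 106 in 5-month males. Col1a1 (Entrez gene 12842, chromosome 11) fell by 2.51 ± 0.13, Col3a1 fell by 2.26 ± 0.22, and the collagen-binding Sparc fell by 2.03 ± 0.19. The class II gene H2-Aa rose by 2.14 ± 0.39, and Cd74, the invariant chain of class II molecules, by 1.29 ± 0.21. Of the 172 probe sets past the threshold, 76 were higher and 96 lower in young adults.

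Extracellular matrix genes fell with 18 of 39 lower and 1 higher (20 and 2 adjusted over the list alone, camera adjusted p = 1.34e-23). Epicardium and fibroblast markers, which share the collagens, fell with 4 of 19 lower (5 adjusted over the list alone), Col1a2 with -1.61 ± 0.13 among them, and Dcn (-0.13 ± 0.12) did not pass. Smooth muscle markers fell with 1 of 11 lower (3 adjusted over the list alone), the smooth muscle actin Acta2 (-1.85 ± 0.21), while Des (-0.14 ± 0.16) and Actg2 (-0.17 ± 0.17) did not pass. Endothelial markers fell with 1 of 20 lower (5 adjusted over the list alone), the nitric oxide synthase Nos3 (-1.45 ± 0.36), with means of 521 ± 110 (SD) at 4 weeks, 117 ± 61.5 in 3-month females and 336 ± 85.5 in 5-month males. Cdh5 (-0.49 ± 0.14), Sox18 (-0.42 ± 0.15) and Eng (-0.32 ± 0.17) did not pass. Imprinted growth genes fell with 2 of 16 lower (3 adjusted over the list alone), Peg3 (-1.07 ± 0.18) and Igf2 (-0.86 ± 0.13). Antigen presentation rose with 3 of 16 higher (7 adjusted over the list alone, adjusted p = 0.0217 with an estimated correlation), the 3rd being H2-K1 (0.75 ± 0.18). Erythroid markers, with 4 lower and 1 higher of 18 (4 and 1 adjusted over the list alone), had adjusted p = 0.173 with an estimated correlation, and cell cycle genes, with 0 of 39 past the test (0 adjusted over the list alone), 0.378.

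The other large rises were Cpxm2 (5.04 ± 0.64), the amylase Amy1 (3.61 ± 0.47), Cyp2b10 (2.72 ± 0.42), the stress factor Ddit3 (2.03 ± 0.50), Tspan4 (1.73 ± 0.22), the growth factor Ccn2 (1.70 ± 0.23) and Nampt (1.5 ± 0.19), an enzyme of NAD synthesis. Ccn2 and Cyp2b10 were highest in 3-month females, with means of 628 and 106 at 4 weeks, 3710 and 1230 in 3-month females and 1040 and 356 in 5-month males. The other large falls were the collagen Col5a2 (-2.0 ± 0.21), Tgfb1 (-1.97 ± 0.51), the water channel Aqp4 (-1.96 ± 0.35) and Csrp2 (-1.94 ± 0.23). The red-cell transcripts Alas2 (-2.37 ± 0.41), Hbb-b2 (-2.13 ± 0.35), Hba-a1 (-1.43 ± 0.29) and Tfrc (-0.88 ± 0.20) were lower in the average of both young adult groups. Hbb-b2 had a mean of 10600 ± 2370 (SD) at 4 weeks, 8970 ± 986 in 5-month males and 823 ± 646 in 3-month females. Against 4 weeks, 84 probe sets passed for 5-month males alone and 277 for 3-month females alone. With 5-month males alone Cyp2b10, Ddit3, Ccn2, H2-K1, Nos3, Aqp4, Tgfb1, Alas2, Hbb-b2 and Hba-a1 did not pass, and 4 of the 8 list calls were lost, those of cell cycle, endothelial, erythroid and imprinted growth genes. With 3-month females alone Ddit3, Tfrc, Tgfb1 and the cell cycle list did not pass. The calls of Ddit3, Tgfb1, H2-K1, Tfrc, Hba-a1 and Nos3 were each lost without some single array, with adjusted p up to 0.284 for Ddit3. The count of 172 fell to 108, 98 and 98 without the 1st, 2nd and 3rd array of 4 weeks, and to 100 with a batch term from hybridization controls. With that term H2-Aa (2.08 ± 0.52), H2-K1 (0.76 ± 0.24), Peg3, Tfrc, Hba-a1, Nos3, Aqp4, Ddit3 and Tgfb1 no longer passed, and the other genes named as past the test did.

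Between young adults and 1 year, few genes changed, among them red-cell transcripts. Fn1 (chromosome 1), which encodes the matrix protein fibronectin, rose by 0.68 ± 0.12 on the log2 scale, from 378 ± 85.8 (SD, n = 3) in 3-month females and 373 ± 38.8 in 5-month males to 589 ± 15.2 in 1-year females and 613 ± 134 in the 1-year m group. Hbb-b2 (1.99 ± 0.29), Alas2 (2.0 ± 0.34) and Hba-a1 (1.38 ± 0.24) passed the test as well, and Tfrc (-0.12 ± 0.16) did not. Their rise lay between the female groups, with Hba-a1 at 3450 ± 2000 in 3-month females, 27300 ± 10400 in 5-month males, 23900 ± 6010 in 1-year females and 22100 ± 2390 in the 1-year m group. In all, 8 probe sets passed, 7 higher and 1 lower at 1 year, with 586 at an unadjusted p under 0.05.

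Camera called 3 lists at 1 year, and none kept its call. Erythroid markers (3 of 18 higher, 3 adjusted over the list alone) had adjusted p = 0.153 with an estimated correlation, antigen presentation (0 of 16, 6 adjusted over the list alone) 0.0578 and oxidative phosphorylation, in the lower direction (0 of 58, 0 adjusted over the list alone), 0.865. Senescence genes were not called, with 0 of 13 past the test and camera adjusted p = 0.32. Without the intensity trend, or with only these 4 groups in the fit, 0 probe sets passed, and 3 passed without the 2nd array of the 1-year m group, 5 without the 3rd of 5-month males and 5 without the 2nd of 3-month females. Fn1 lost its call without each of these 3 arrays, with adjusted p up to 0.403 over all alternatives.

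In females, the oxygen-carrying globins were higher at 1 year than at 3 months, and Nppb, Acta1 and Rrad were lower. Hbb-b2 (Entrez gene 15130, chromosome 7) rose by 3.62 ± 0.40 on the log2 scale, from 823 ± 646 (SD, n = 3) to 7730 ± 485, with Alas2 (3.63 ± 0.47), the enzyme that starts haem synthesis in red cells, and Hba-a1 (3.00 ± 0.34). The natriuretic peptide Nppb fell by 1.40 ± 0.27 on the log2 scale, from 20800 ± 3830 to 7830 ± 1100, the skeletal actin Acta1 by 1.16 ± 0.23 and the GTPase Rrad by 1.30 ± 0.17. Nppb was high in 3-month females alone, with means from 5030 to 8910 in all other groups, so its fall reflects that group. Acta1 and Rrad were instead lowest among adults in 1-year females, with means of 5830 and 2840. Of 37 probe sets past the threshold, 24 were higher and 13 lower. Probe sets of globin genes share sequence, so which globin was measured is uncertain.

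The other rises in females were the chemokine Ccl5 (2.19 ± 0.43), Tent5c (2.27 ± 0.41), Slc27a4 (2.17 ± 0.44), Eef2k (2.11 ± 0.47) and the pseudogene Tyms-ps (2.62 ± 0.41), for which another probe set had the opposite sign. Ccl5 had means below the background level of 125 in both groups (21.3 to 107). The other falls were the cell cycle factor Foxm1 (-1.82 ± 0.24), the desaturase Scd1 (-1.53 ± 0.29), Prrg2 (-1.52 ± 0.31), Hbegf (-0.99 ± 0.20) and Mcrip1 (-0.99 ± 0.19). Scd1 too was high in 3-month females alone, with a mean of 2300 against 167 to 735 in the other groups. Camera called 5 lists, and none kept its call. Antigen presentation (1 of 16 higher, H2-D1 with 0.79 ± 0.17, and 5 adjusted over the list alone) and fetal cardiac genes (2 of 13 lower, 4 adjusted over the list alone) each had adjusted p = 0.0797 with an estimated correlation. Atrial markers (0 of 11, 2 lower adjusted over the list alone) had adjusted p = 0.306 with an estimated correlation, with Nppa at -1.11 ± 0.28, Myl7 at -0.87 ± 0.92 and Myl4 at -0.04 ± 0.52, none past the test. Erythroid markers (3 of 18 higher, 3 higher and 1 lower adjusted over the list alone), where Tfrc had -0.37 ± 0.23, had adjusted p = 0.508 and fatty acid oxidation (0 of 30, 2 higher adjusted over the list alone) 0.631 with an estimated correlation.

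The 3-month females also stood apart in a technical measure. The log2 ratio of the hybridization controls BioB and BioC lay between -0.28 and -0.09 on their arrays and was -0.23 and -0.35 on the 2nd and 3rd arrays of the 1-year m group, against -0.82 or lower on the other 19 arrays. Among adult samples, the titles of these arrays of high ratio carry single-digit numbers and the others longer ones. E12.5 titles carry single-digit numbers too, with the low ratio. The labels do not say what the numbering means, so it is not known whether the split marks hybridization alone. With this split as a batch term, 0 probe sets passed between 1-year and 3-month females in place of 37. The fold of Hbb-b2 was then 4.07 ± 0.73, that of Nppb -1.43 ± 0.50 and that of Tyms-ps 0.48 ± 0.52, all with larger errors. Only 1 probe set passed with only these 6 arrays in the fit and 15 passed without the intensity trend, while 18 and 69 passed without the 2nd and 3rd arrays of 3-month females, and 14 and 11 without the 2nd and 3rd of 1-year females. Of the genes named for this comparison, Hbb-b2, Alas2, Hba-a1, Rrad, Foxm1 and Tyms-ps kept their call without any single array, and the others did not.

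**Figure D4:**
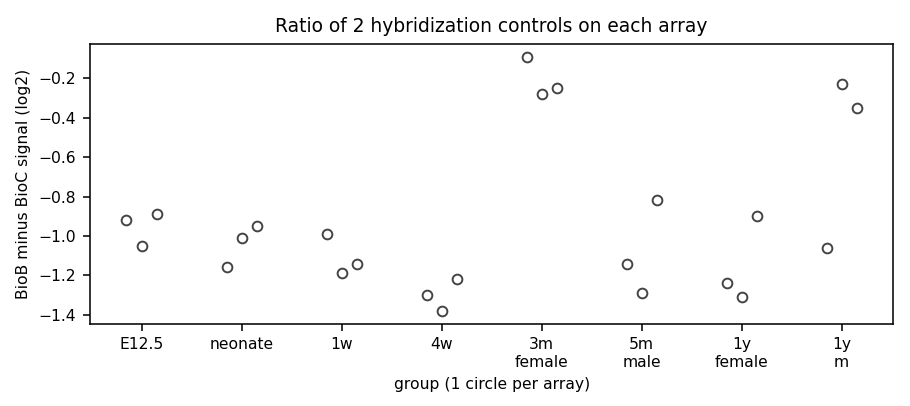
Log2 ratio of the hybridization controls BioB and BioC (vertical axis) on each of the 24 arrays, by group along the horizontal axis, with 1 circle per array. The ratio was -0.35 or higher on 5 arrays, the 3 of 3-month females and the 2nd and 3rd of the 1-year m group, and -0.82 or lower on the other 19.

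Between 5-month males and the 1-year m group, 1 probe set passed, with 897 at an unadjusted p under 0.05. Pold1 (chromosome 7), the catalytic subunit of DNA polymerase delta, fell by 1.76 ± 0.25 on the log2 scale, from 340 ± 109 (SD, n = 3) to 99.7 ± 26.2. Camera called 10 lists, and fetal cardiac genes kept their call as higher in the 1-year m group, with adjusted p = 0.0228 with an estimated correlation although 0 of 13 members passed (3 adjusted over the list alone). Atrial markers (0 of 11, 3 adjusted over the list alone), complement and acute phase genes (0 of 11 by either adjustment) and imprinted growth genes, the last in the lower direction (0 of 16, 1 adjusted over the list alone), each had adjusted p = 0.0862 with an estimated correlation. Members that did not pass were Myl7 (3.73 ± 0.92), Myl4 (1.87 ± 0.52) and Nppa (1.11 ± 0.28), and the 3 arrays of the 1-year m group ranged from 103.3 to 5081.1 for Myl7. Contractile genes (0 of 21), fatty acid oxidation (0 of 30), glycolysis (0 of 15) and oxidative phosphorylation (0 of 58, 3 lower adjusted over the list alone) were called lower, with adjusted p = 0.101, 0.42, 0.418 and 0.272 with an estimated correlation. T and B lymphocyte markers (0 of 15, 1 adjusted over the list alone) and erythroid markers (0 of 18) were called higher, with adjusted p = 0.272 and 0.418 with an estimated correlation. Their members not past the test were Ighm (1.02 ± 0.25), Cd79a (0.61 ± 0.41), Ms4a1 (0.02 ± 0.31), Hbb-b2 (0.35 ± 0.40), Tfrc (0.13 ± 0.23) and Hba-a1 (-0.24 ± 0.34). Without the 1st array of the 1-year m group 94 probe sets passed, without the 3rd 4, and without the 1st array of 5-month males 3. With only these 6 arrays in the fit 0 passed, and Pold1 was not called without the 2nd array of 5-month males either.

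The difference in ageing between the sexes was tested as the change from 3-month to 1-year females minus that from 5-month males to the 1-year m group, although the young groups differ in age as well as in sex. Fetal cardiac genes moved apart: Nppa had a difference of -2.23 ± 0.40 on the log2 scale, Nppb (chromosome 4) of -1.96 ± 0.38 and Acta1 of -1.47 ± 0.32. Nppa read 2960 ± 252 (SD, n = 3) in 3-month females and 1390 ± 353 in 1-year females, against 1030 ± 297 in 5-month males and 2490 ± 1680 in the 1-year m group. For Nppb the difference came mainly from 3-month females, with a mean of 20800. It had 6410 in 5-month males, 7830 in 1-year females and 8910 in the 1-year m group. The red-cell transcripts Hbb-b2 (3.27 ± 0.57) and Alas2 (3.27 ± 0.67), Tyms-ps (3.94 ± 0.58), Cdc42ep4 (3.38 ± 0.71) and the lipase Lpl (1.89 ± 0.42) had positive differences, and the adhesion molecule Icam5 (-3.49 ± 0.85) a negative difference. Mean signals of Tyms-ps, Cdc42ep4 and Lpl went up in females and down from 5-month males to the 1-year m group, as with Lpl from 6560 to 14300 and from 15900 to 10200. Those of Icam5 went from 197 to 39.8 in females and from 89.4 in 5-month males to 169 in the 1-year m group. In all, 108 probe sets passed, 60 higher and 48 lower.

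Fetal cardiac genes were called as a list, with 3 of 13 lower (6 adjusted over the list alone) and adjusted p = 0.0071 with an estimated correlation. Myl7, Myl4 and Nppa stand both in this list and in the atrial one. The other 5 called lists lost their call. Atrial markers (1 of 11 lower, 5 adjusted over the list alone) had adjusted p = 0.0522 with an estimated correlation, with Myl7 at -4.60 ± 1.30 and Myl4 at -1.91 ± 0.74, neither past the test. Imprinted growth genes (1 of 16 higher, Cdkn1c with 1.41 ± 0.35, and 3 adjusted over the list alone) had adjusted p = 0.0763 with an estimated correlation, and contractile genes (0 of 21, 5 adjusted over the list alone) 0.18. Fatty acid oxidation (1 of 30, 8 higher and 1 lower adjusted over the list alone) had adjusted p = 0.442 with an estimated correlation. Oxidative phosphorylation (5 of 58, 10 higher and 1 lower adjusted over the list alone), with Uqcrq at 1.12 ± 0.27, Atp5l at 1.08 ± 0.26 and Ndufb8 at 1.08 ± 0.24, had 0.51, and another probe set of Atp5l had the opposite sign. Of the 108 probe sets, 35 also differed between 3-month females and 5-month males, a comparison added after the data were seen in which 84 passed, and 12 between the 1-year groups. The ageing by sex comparison is made of these same differences, so some overlap follows from the shared arrays and is no separate support. Across probe sets, which are not independent replicates, the change in females and that from 5-month males to the 1-year m group had Pearson r = -0.115 and Spearman rho = -0.138.

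With the batch term 0 probe sets passed in place of 108, and the median SE rose from 0.579 to 1.17. The folds of Hbb-b2 (4.01 ± 1.17), Nppb (-2.0 ± 0.80), Acta1 (-1.49 ± 0.66) and Icam5 (-3.13 ± 1.76) then lay near those without it, and that of Alas2 (4.41 ± 1.37) was larger. Those of Tyms-ps (0.37 ± 0.83), Nppa (-0.58 ± 0.72), Lpl (-0.31 ± 0.67), Cdc42ep4 (-0.28 ± 1.19), Cdkn1c (-0.29 ± 0.59), Uqcrq (-0.03 ± 0.49), Atp5l (0.05 ± 0.47) and Ndufb8 (0.11 ± 0.44) were smaller in size. As the term rests on the 1st array of the 1-year m group against its 2nd and 3rd, these folds show little either way. With only these 4 groups in the fit 1 probe set passed and without the intensity trend 27. Leaving out the 1st, 2nd or 3rd array of the 1-year m group gave 347, 19 and 47, of 5-month males 61, 55 and 41, and of 1-year females 43, 37 and 30, and leaving out the 3rd of 3-month females gave 42. Tyms-ps, Hbb-b2 and Nppa kept their call without any single array.

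At 1 year, few genes differed between females and the m group, and antigen presentation was higher and fetal cardiac genes lower in females as lists. Ddit4 (Entrez gene 74747, chromosome 10), an inhibitor of the mTOR kinase pathway, was higher by 2.70 ± 0.35 on the log2 scale, with 2590 ± 226 (SD, n = 3) against 488 ± 394. The transcription factor Cebpb (1.44 ± 0.25), the kinases Map3k6 (2.78 ± 0.57) and Sgk1 (1.18 ± 0.25), Errfi1 (1.18 ± 0.24), Dpysl3 (2.24 ± 0.45), Pold1 (1.94 ± 0.25) and the X-linked demethylase Kdm6a (1.32 ± 0.27) were higher as well. Foxm1 (-1.57 ± 0.24), the DNA methyltransferase Dnmt1 (-1.83 ± 0.39), Cd276 (-2.06 ± 0.40), Acta1 (-1.11 ± 0.23) and Rrad (-1.07 ± 0.17) were lower. Of 21 probe sets past the threshold, 16 were higher and 5 lower. Xist, with a difference of 5.41 ± 1.19, missed the threshold with adjusted p = 0.0549, in a fit whose pooled spread includes the mixed neonate and 1-week arrays, and the differences of Eif2s3y (-3.11 ± 1.06), Uty (-2.38 ± 0.86) and Kdm5d (0.15 ± 0.67) did not pass either.

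Antigen presentation was higher in 1-year females, with 1 of 16 members past the test, H2-D1 (0.81 ± 0.17), and 7 adjusted over the list alone. Fetal cardiac genes were lower, with 1 of 13 (1 adjusted over the list alone), and both lists had adjusted p = 0.0494 with an estimated correlation. Interferon response genes (0 of 19, 1 higher adjusted over the list alone) had adjusted p = 0.0502 with an estimated correlation. Ribosomal proteins (0 of 28, 0 adjusted over the list alone) had 0.576 and atrial markers, called lower (0 of 11, 0 adjusted over the list alone), 0.436 with an estimated correlation. Myl7 (-1.06 ± 0.92), Myl4 (-0.69 ± 0.52) and Nppa (-0.67 ± 0.28) did not pass. With the batch term 1 probe set passed, Pold1 (2.39 ± 0.34), and with only these 6 arrays in the fit 0. The folds of Ddit4 (1.46 ± 0.34), Errfi1 (0.71 ± 0.32), Kdm6a (0.67 ± 0.34) and Sgk1 (0.55 ± 0.31) were then smaller, and those of Map3k6 (3.28 ± 0.81) and Dnmt1 (-2.26 ± 0.54) larger in size. Leaving out the 1st, 2nd or 3rd array gave 119, 7 and 10 for the 1-year m group and 12, 6 and 5 for 1-year females. Ddit4, Pold1, Foxm1 and Rrad kept their call without any single array.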

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

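The results in this part stand out because the change with age differed between the sexes by a test of the difference itself, the ageing by sex comparison. The tests of blood, of atrial tissue and of 2 arrays left out were chosen after the results they concern had been seen, and the splits of the arrays were set before. The correlation for the hybridization batch was set before it was computed, but it rests on control ratios and a count of calls already seen. The young females were 3 months and the young males 5 months old, and the sex of the 1-year m group rests on its titles and on Xist, so sex, age and batch are not separated by the design.

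In the ageing by sex comparison 108 probe sets passed, more than the 37 for 1-year against 3-month females and the 1 for the 1-year m group against 5-month males. The genes named were Tyms-ps (3.94), Cdc42ep4 (3.38), Hbb-b2 (3.27), Alas2 (3.27), Lpl (1.89), Cdkn1c (1.41), Uqcrq (1.12), Atp5l (1.08), Ndufb8 (1.08), Acta1 (-1.47), Nppb (-1.96), Nppa (-2.23) and Icam5 (-3.49), as log2 differences of the change in females minus that from 5-month males to the 1-year m group. With the batch term Cdc42ep4, Lpl, Cdkn1c and Uqcrq changed sign and Tyms-ps fell to 0.37, while Atp5l changed sign with the mean over its probe sets. The lists called had mean log2 differences of 0.63 for contractile genes, 0.35 for fatty acid oxidation, 0.53 for imprinted growth genes, 0.24 for oxidative phosphorylation, -1.03 for fetal cardiac genes and -1.67 for atrial markers. Of these, only fetal cardiac genes kept their call with an estimated correlation. Myl7 (-4.6) and Myl4 (-1.91), neither past the test, and Nppa stand in the fetal and in the atrial list, while Nppb and Acta1 stand in the fetal list only. The fetal list was not tested without the shared genes, so atrial tissue in some samples may bear on its call.

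For the size of this comparison, a hybridization batch and 2 single arrays were weighed, the 3rd of 3-month females and the 2nd of the 1-year m group, which correlated best with each other (r = 0.927 across probe sets, against 0.912 and 0.923 within their groups), while the other 1-year m arrays correlated best with a 5-month male array (0.938 and 0.93). The batch is marked by the BioB to BioC control ratio, which was high on all arrays of 3-month females and on the 2nd and 3rd of the 1-year m group, the groups that enter with the same sign. If the batch moved the same genes in both, the difference between the 1-year m arrays of high and low ratio should follow that between 3-month females and 5-month males. The correlation across probe sets was r = 0.134, against -0.139 and 0.00714 when another 1-year m array took the place of the 1st. These differences are built from the same 1-year m arrays and cancel out when added, so the correlations are not independent of each other. Leaving out these 2 arrays left 21 calls, but leaving out 1 array from each of these groups in other pairs left from 15 to 365, so the test does not single these 2 out. The counts followed the control ratio of the 1-year m array left out. Pairs with the 1st, of low ratio, left 222 to 365 calls, and pairs with the 2nd or 3rd, of high ratio, left 15 to 45. More probe sets thus passed where only arrays of high ratio stood for the 1-year m group. The batch, single arrays and a biological difference of sex or age, which was not tested apart from them, all stay open, and with the batch as a term 0 probe sets passed by limma (1268 at an unadjusted p under 0.05 without the term) while the SE doubled to 1.17.

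Chance as the source of the 108 calls was tested by regrouping the 12 adult arrays. Of 100 splits, 2 had as many calls, the real one included, with 200 calls in the other split. The splits mixed all 4 adult groups, so they ask whether these groups differ in any way. They cannot exclude chance for the ageing by sex difference itself. The split with 200 calls set all 5 arrays of high control ratio, the 3 of 3-month females and the 2nd and 3rd of the 1-year m group, on the same side, as the real comparison also does. It follows the hybridization batch, which points to a structure of these arrays besides age and sex.

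Red-cell transcripts were low in 3-month females, with Hbb-b2 at -3.88 on the log2 scale against the other adults. The tests argue against a hybridization batch as the cause, provided that it is the same batch on all arrays of high ratio. In the 1-year m group these arrays read 0.44 higher, not lower, for Hbb-b2 than the single array of low ratio (16553 and 9672.4 against 9299.5). The tests also argue against a constant difference between females and males as the whole cause. Hbb-b2 was -0.57 (SE 0.404) in females against the m group at 1 year and -3.83 ± 0.40 between the young groups, and the ageing by sex difference was 3.27 ± 0.57. Less blood in the samples may be the source, and 18 leukocyte transcripts, which should fall with it, had a mean difference of 0.21 (SE 0.109) from 5-month males, with 4 lower. Most of these lay below the background level of 125, so the test does not decide, and perfusion, bleeding or an age difference in blood formation cannot be told apart here.

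The atrial light chain Myl7 ranged from 38.1 to 5081.1 among adult ventricle arrays, and the spread within groups was large. Atrial tissue in some samples is a candidate explanation: over 15 arrays from 4 weeks on, the mean within-group Pearson r of Myl7 with 10 other atrial markers was 0.323 (1-sided permutation p = 0.0281, which would miss 0.05 if doubled, 7 positive, 0.356 without the 2 farthest arrays). No marker passed alone, with Myl4 at r = 0.746 and rho = 0.714 (permutation p = 0.0267, BH-adjusted 0.134), Nppa at r = 0.452 and Sln, abundant in atria, at -0.101. The hybridization batch is argued against, since the 2nd and 3rd arrays of the 1-year m group, both of high ratio, differed by 5.62 on the log2 scale. Higher Myl7 expression in the ventricle itself was not tested and stays open. Of the atrial list, Myl7, Myl4 and Nppa are also fetal cardiac genes, so atrial tissue could bear on the calls of the fetal list among adults too.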

How the results depend on the processing

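The alternatives were fixed before the data were examined, except the batch term, the 2 arrays left out together and the young adult groups taken alone, which were chosen after seeing the data. With 37.9% of the tested values below the background level of 125, folds of dim genes depend on the floor, and 3 arrays per group limit the precision. Of 215 named gene calls 102, and of 74 list calls 52, passed under every alternative fixed in advance that tested them (for lists, besides the estimated correlation). Of 253 named gene results, called or not, the stricter filter tested 239 and the floor at the 40th percentile 252. A gene that a filter removed could therefore still be counted among the 102. Except where a value is given here, the cause of a change was not tested.

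A minimum of 2-fold, which by construction only removes calls, left 921 for neonate against E12.5, 115 for 1 week against neonate, 440 for 4 weeks against 1 week, 83 for young adults against 4 weeks and 23 for 1-year against 3-month females. Without the intensity trend the counts were 121 at 1 week, 102 in young adults, 0 at 1 year (limma, 586 at an unadjusted p under 0.05 with the trend), 15 for ageing in females and 27 for the ageing by sex comparison. With array weights they were 384 in young adults, 76 for ageing in females, 2 for the m group against 5-month males and 37 between the 1-year groups. With only the groups compared in the fit, which leaves fewer arrays to estimate the spread, they were 16 at 1 week, 586 at 4 weeks, 0 at 1 year, 1 for ageing in females, 0 for the m group against 5-month males, 1 for ageing by sex and 0 between the 1-year groups. An estimated correlation left 37 of the 74 list calls.

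The batch term is partly confounded with the groups and was estimated within the 1-year m group alone. With it the counts were 100 in young adults, 0 for ageing in females, 5 for the m group against 5-month males, 0 for ageing by sex and 1 between the 1-year groups. Without the 3rd array of 3-month females and the 2nd of the 1-year m group they were 259 in young adults, 14 at 1 year, 74 for ageing in females, 21 for ageing by sex and 6 between the 1-year groups. Against 4 weeks, 5-month males alone gave 84 and 3-month females alone 277. Leaving out each array in turn gave from 109 to 240 at 1 week, 98 to 223 in young adults, 3 to 11 at 1 year, 11 to 69 for ageing in females, 1 to 94 for the m group against 5-month males, 19 to 347 for ageing by sex and 5 to 119 between the 1-year groups. For the other counts it gave 1252 to 1473 for neonate against E12.5, 631 to 838 at 4 weeks, 3400 to 3981 for the F test and 69 to 78 for the list calls.

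Signs changed mostly in genes that had not passed. For the m group against 5-month males these were Ms4a1 (-0.011) and Hba-a1 (0.14) under quantile normalization, and Tfrc with the mean over probe sets (-0.21), the batch term (-0.054) and without the 2 arrays (-0.059). For ageing in females Myl4 had 0.22 with array weights, 0.44 with the batch term and 0.56 without the 2 arrays. Between the 1-year groups Kdm5d was 0 with the floor at the 40th percentile, where both groups lie at the floor, and Myl7 was 0.29 without the 2 arrays. In young adults against 4 weeks Dcn had 0.033 with the batch term, Hba-a1, which had passed, 0.14 with 5-month males alone and Actg2 0.0043 with 3-month females alone. For ageing by sex too, genes that had passed changed sign: Atp5l with the mean over its probe sets (-0.072), and Cdc42ep4 (-0.28), Lpl (-0.31), Cdkn1c (-0.29) and Uqcrq (-0.027) with the batch term.

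Leaving out each array in turn, signs changed for Ms4a1 (-0.094 to 0.17), Tfrc (-0.059 to 0.23) and Hba-a1 (-0.50 to 0.045) for the m group against 5-month males, and for Tfrc at 1 year (-0.21 to 0.0049). They also changed for Myl4 in ageing in females (-0.89 to 0.56), for Kdm5d (-0.23 to 0.47) and Myl7 (-2.52 to 0.29) between the 1-year groups, and for Hbb-b2 (-0.43 to 0.032) and Hba-a1 (-0.017 to 0.27) in neonate against E12.5.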

Other observations

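The biology here was looked for after the report's comparisons had been made, and the test of glucocorticoid-responsive genes and the comparison of the young adult groups were chosen after the results had been seen. The splits of the arrays were set before the data were examined.

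Between the young adult groups, 3-month females and 5-month males, 84 probe sets passed by limma, 34 higher and 50 lower in females. Besides the red-cell transcripts Hbb-b2 (-3.83 ± 0.40, SE), Hba-a1 (-3.15 ± 0.34) and Alas2 (-4.14 ± 0.47), the genes of oxidative metabolism Acaa2 (-0.76 ± 0.16), Idh2 (-0.62 ± 0.14) and Lpl (-1.26 ± 0.29) and the opioid precursor Penk (-1.30 ± 0.18) were lower in females. The natriuretic peptides Nppb (1.77 ± 0.27, 20800 against 6410) and Nppa (1.56 ± 0.28), the desaturase Scd1 (2.30 ± 0.29), the growth factor Ccn2 (1.84 ± 0.26) and Xist (4.90 ± 1.19, adjusted p = 0.0485) were higher. Matrix genes went both ways, with Lum (0.96 ± 0.21) and Mgp (0.76 ± 0.18) higher and Col1a1 (-0.64 ± 0.15) and Col4a1 (-0.63 ± 0.15) lower. These genes were chosen after their values were seen. All 3 arrays of 3-month females also had the high hybridization control ratio, and none of the 5-month males did, so age, sex and batch are confounded here. Of the 37 calls for ageing in females, 8 had a fold of the same sign from 5-month males to the 1-year m group, where 1 probe set passed. The arrays of high control ratio lie on the young side in females and on the old side in that comparison, so a batch effect would turn signs apart.

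In neonates and at 1 week single arrays differed in their sex-linked transcripts. Xist read from 12.8 to 2495.6 among neonate arrays and from 51.9 to 1244 at 1 week, with Eif2s3y from 11.9 to 535.8 and from 6.0 to 336.1. At 4 weeks Xist was at most 23.9 on the 3 arrays and Eif2s3y at least 236.8. At E12.5 Xist was at least 885.7 and Eif2s3y from 108.1 to 335. Comparisons of these groups therefore include the sex of the samples, which the labels do not give.

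At 1 year, a glucocorticoid-like response in females is a candidate explanation for the higher Ddit4, Cebpb, Sgk1, Errfi1 and Map3k6 there. A list of 13 other glucocorticoid-responsive genes was tested, and 11 were higher in females than in the 1-year m group, with a median log2 difference of 0.48 and a mean of 0.38. Camera gave p = 0.000318, or 0.00377 with an estimated correlation and 0.00138 with the batch term. Genes called in this comparison were kept out of the list, so by construction no gene of it passed alone. Fkbp5 came closest with 1.08 ± 0.25 (limma adjusted p = 0.0852). Tsc22d3, a glucocorticoid-induced gene, went the other way with -0.81 ± 0.59 (61.8 against 121.9), as did Angptl4 with -0.15 ± 0.36. With the batch term the genes that prompted it were smaller for Ddit4 (1.46 ± 0.34), Cebpb (1.20 ± 0.35), Sgk1 (0.55 ± 0.31) and Errfi1 (0.71 ± 0.32) and larger for Map3k6 (3.28 ± 0.81), and none of them passed. The hypothesis was formed and tested on the same arrays, hormone levels and the time of day of sampling are not given in the sources used here, and other stress responses share these genes.

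Other splits of the same arrays into groups of the same sizes were counted. For any difference among the 8 groups, 1 of 100 splits had as many calls, the real 3883 against at most 5 in another, so chance can be excluded. For young adults against 4 weeks, 3 of 100 splits had as many calls as the real 172, and the highest other had 278. These splits also mixed 3-month females with 5-month males, so they speak to any difference among the groups and cannot exclude chance for age alone. That highest split exchanged the 4-week arrays with those of 3-month females, which points to a structure of the 3-month female arrays. For both 1-year groups against young adults, 6 of 100 splits had as many calls as the real 8, so chance cannot be excluded. The highest other had 114, and splits that placed the 2nd and 3rd arrays of the 1-year m group with 3-month females followed the hybridization control ratio. With the batch term, 9 probe sets passed in that comparison. For the list tests, 19 of 100 splits had as many calls as the real 74, with 101 as the highest other, so chance cannot be excluded for their total. These regroupings mix ages, and a list that differs between ages can be called in them.

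The comparisons of 3 with 3 arrays allow 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 1687 and 7 for neonate against E12.5, 209 and 2 for 1 week against neonate, 909 and 1 for 4 weeks against 1 week, 37 and 0 for ageing in females and 21 and 2 between the 1-year groups, with 1 split as large in each, the real one. For the m group against 5-month males they were 1 and 2, with 4 splits as large. List calls at the preset correlation were not rare in the other splits. The highest other split had 11 for neonate against E12.5 (real 11 up and 5 down) and 5 for 1 week against neonate (real 5 up and 1 down). For 4 weeks against 1 week it had 10 (real 7 up and 8 down), and for ageing in females 8 (real 3 up and 2 down). For the m group against 5-month males it had 7 (real 5 up and 5 down), and between the 1-year groups 4 (real 3 up and 2 down).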
